A study of Mus musculus with 4 samples.

How the data were processed

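RNA from mouse optic nerves was measured in 4 libraries, 2 with the genotype label Dor WT and 2 with the label Dor cKO. Per the labels, RNA was extracted with TRIzol, 2 micrograms of total RNA went into a stranded mRNA library kit, products of 200 to 500 bases were selected, and paired reads of 150 bases were made on a NovaSeq 6000 instrument. Sex, age, strain, the number of animals per library and the driver of the conditional deletion were not given in the sources used here. The names of the Dor WT tables carry a tag that reads like an age and those of the Dor cKO tables do not; what it stands for was not given.

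The submitters' processing notes name Trimmomatic 0.36, STAR 2.7.9a, RSEM 1.3.1 and the mouse build GRCm38, without saying what each tool did. The annotation release was not given in the sources used here. Per the file headers, the deposited tables are RSEM gene tables that give for each gene an expected count and a TPM value, together with its length, effective length and the posterior standard deviation of its count. An expected count is an estimate that shares reads between genes they fit equally well, so it need not be whole, and TPM is scaled by the authors' pipeline to sum to the same total in each library. Whether counting used the strand of the reads was not given in the sources used here, so genes that overlap on opposite strands, such as Xist and Tsix, share an uncertain part of their reads. The mean fragment length of a library was taken as the median over genes longer than 3000 bases of the difference between length and effective length, plus 1. Each table lists 55401 genes. Symbols and coordinates came from GENCODE M21, which is on the same build, and matched 55141 of the 55401 identifiers without regard to version, 54349 of them with the same version. The 260 genes without a symbol held 0.00297% of the counts of the 4 libraries and stayed in the tests.

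The deposited expected counts were rounded to whole numbers. Totals were 17263830 and 21595832 for Dor WT and 21162594 and 20928332 for Dor cKO, so a floor of 3 counts lies between 0.139 and 0.174 CPM. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 at its default minimum count of 10 and minimum total count of 15, which left 16751 genes. Libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood test with a robust fit, group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Fold changes are log2 values coded as Dor cKO minus Dor WT, the standard error (SE) of a fold change is its size divided by the square root of the F statistic, and CPM values use the TMM-scaled library sizes, given as mean ± SD over the 2 libraries of a group. The common biological coefficient of variation was 0.03477.

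Before the data were examined, the test, its alternatives, 39 gene lists and the rule for naming genes were fixed. The lists cover the oligodendrocyte lineage and its stages, other cell types of the nerve, metabolic and stress pathways, and tissues or signs of handling that could enter the samples. For each list the number of tested members past the threshold is given over all genes and adjusted over the list alone, with the median fold change and the competitive test camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists with at least 5 tested members. The test was repeated with an estimated correlation. The self-contained test fry was also run, which asks whether a list's genes move on balance in one direction and does not compare them with other genes. Named genes were both candidates for the deleted gene, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM whose groups did not overlap (genes named by number or clone and pseudogenes excepted), up to 4 called members per list with the highest mean CPM (or the most abundant members where fewer than 2 were called), and the sex chromosome markers. Some genes that this rule selects are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

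The labels name the deleted gene only as Dor. Dor is a known synonym of Trp53inp2, and DOR is listed as a synonym of Oprd1, so both are reported. Counts per gene cannot show the loss of single exons.

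Alternatives were the DESeq2 1.42.0 Wald test, RLE scaling, scaling by total count, no low-count filter, a minimum of 1 CPM in 2 libraries, limma on log2(TPM + 1) from the deposited TPM values, a fit without the robust option, a replicate block, leaving out each library in turn, leaving out mitochondrial and haemoglobin genes, and a minimum absolute log2 fold change of 1. After the data were seen, the removal of a trend on transcript length and GC content was added. A likelihood ratio test with the biological coefficient of variation set at 0.1 was added as well. The steps were tested on simulated data made from the means and sizes of the 4 libraries. Every gene had the same dispersion, and 50 genes were changed at each of 4 sizes. Among 16751 genes, edgeR recovered 18% of the genes changed by 0.2, 52% at 0.3, 74% at 0.5 and 82% at 1 on the log2 scale. Of its 117 calls, 3.42% were false. In the data a far larger share of genes was called (27.7%), so these rates need not hold there. R was version 4.3.3.

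Libraries of a group were compared before they were averaged, over genes without shared reads and with at least 20 counts summed over the pair. The mean squared difference was 2.34 times counting error between the Dor WT libraries and 1.91 times between the Dor cKO libraries. Between groups it was 28.6 and 31.6 times. Each library was kept as a sample, although these values do not show that the libraries of a group are independent. Separate preparations of the same RNA could also differ by more than counting error. Floors cover counting error only. Reads shared between near-identical genes make some values uncertain: the largest posterior SD of a library was 9.62% of the count for Tgtp1 and 8.2% for Gbp10.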

Results

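The data describe gene expression in the mouse optic nerve, a tract of retinal ganglion cell axons that are wrapped in myelin by oligodendrocytes and accompanied by astrocytes, microglia, vessels and a meningeal sheath. There were 2 libraries with the genotype Dor WT and 2 with the genotype Dor cKO, a conditional knockout. Total expected counts were 17263830 and 21595832 in Dor WT and 21162594 and 20928332 in Dor cKO, and between 21889 and 22547 genes had counts above 0. The names of the deposited Dor WT tables carry a tag that reads like an age, and those of the Dor cKO tables carry none. The labels give no age or batch for either group. Across genes, log2 CPM values correlated at 0.9949 within Dor WT and 0.9957 within Dor cKO, against 0.9884 to 0.9892 between groups, where genes are not independent replicates. The title of the study places the question in the control of alpha-ketoglutarate metabolism in mature oligodendrocytes and of myelination.

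The targeted gene was examined in every library. Trp53inp2 (ENSMUSG00000038375.15; GRCm38 chromosome 2, 155381059 to 155389850), which encodes a nuclear and autophagy-associated protein also called Dor, had 138 and 134 CPM in Dor WT and 105 and 107 CPM in Dor cKO. It fell by 0.36 on the log2 scale (SE 0.04, edgeR adjusted p = 2.73e-08), 1.28-fold lower with 2 libraries per group. The call ended with limma on log2(TPM + 1), at a log2 fold change of -0.28 and an adjusted p of 0.078, and with the coefficient of variation set at 0.1, at an adjusted p of 0.111. Oprd1, the opioid receptor gene that shares the synonym, had counts of 4 and 2 in Dor WT and 5 and 0 in Dor cKO and was too low to test. The counts cover the whole gene in whole tissue and so do not by themselves check a deletion limited to some cells or exons.

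Genes of the oligodendrocyte lineage and of myelin were lower in Dor cKO, and interferon responsive genes were higher. Mobp (chromosome 9, 120149707 to 120181484), which encodes a structural protein of central myelin, went from 2662 ± 9.60 CPM to 1475 ± 11.01 CPM (SD, n = 2 per group), 1.81-fold lower. Olig1, a transcription factor of the lineage, went from 380 ± 0.544 to 151 ± 1.32 CPM, 2.52-fold lower. Isg15, which encodes a ubiquitin-like modifier induced by interferon, went from 4.43 and 4.24 CPM in Dor WT to 15.9 and 18.2 CPM in Dor cKO, 3.93-fold higher. Of 16751 genes tested, 2399 were higher and 2248 lower at an edgeR adjusted p under 0.05, or 27.7% of those tested. Most of these changes were small: 2087 of the higher and 1739 of the lower genes changed by less than 1.5-fold, and 123 rose and 172 fell by at least 1 on the log2 scale.

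Among myelin and mature oligodendrocyte genes, 32 of 40 tested members fell, 4 rose and 4 did not pass, with a median log2 fold change of -0.72. Adjusted over the list alone, 32 fell and 5 rose. The list stood below other genes by camera (adjusted p = 5.78e-84, and adjusted p = 0.0483 with an estimated correlation) and moved down on balance by fry (adjusted p = 0.00167). Mbp, which encodes a protein that compacts the myelin sheath, went from 15648 ± 37.6 to 9450 ± 50.7 CPM and fell by 0.73 (SE 0.01, adjusted p = 2.97e-31). Mobp fell by 0.85 (SE 0.01), and Cnp, which encodes an enzyme of the non-compact myelin, fell by 0.75 (SE 0.01). Ermn, a cytoskeletal gene of mature oligodendrocytes, fell by 1.53 (SE 0.06, adjusted p = 2.15e-17).

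The oligodendrocyte lineage transcription factors fell in 14 of 15 tested members and rose in 0, with the same counts adjusted over the list alone and a median of -0.81 (camera adjusted p = 8.05e-33, and adjusted p = 0.0483 with an estimated correlation). Olig1 fell by 1.33 (SE 0.03, adjusted p = 1.04e-24). Myrf, which drives the myelin programme, fell by 0.82 (SE 0.03), Sox10, which specifies the lineage, by 0.76 (SE 0.03) and Zeb2 by 0.52 (SE 0.03). Genes of newly formed oligodendrocytes fell in 24 of 27 members and rose in 1, or 25 and 1 adjusted over the list alone, with a median of -0.69 (camera adjusted p = 3.31e-69, and adjusted p = 0.0483 with an estimated correlation). Among them, Gpr17, a receptor of cells about to differentiate, fell by 1.18 (SE 0.02), Bcas1 by 1.11 (SE 0.02), the deacetylase gene Sirt2 by 0.74 (SE 0.02) and Tns3 by 0.53 (SE 0.02).

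Of 23 oligodendrocyte precursor genes, 12 fell, 1 rose and 10 did not pass, or 13 and 2 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 3.4e-05, and adjusted p = 0.146 with an estimated correlation). Vcan, which encodes a matrix proteoglycan, fell by 0.60 (SE 0.03), Fabp7, a fatty acid binding protein gene, by 0.30 (SE 0.03), and Pdgfra, the growth factor receptor that marks precursors, by 0.07 (SE 0.03, adjusted p = 0.044). The Pdgfra call was lost with DESeq2 (adjusted p = 0.174), without Dor WT replicate 1 (-0.04, adjusted p = 0.363), Dor cKO replicate 1 (adjusted p = 0.175) or Dor cKO replicate 2 (adjusted p = 0.19), and with the trend on length and GC content removed (-0.0117, adjusted p = 0.803). Of 35 cell cycle genes, 7 fell and 1 rose, with the same counts adjusted over the list alone and a median of -0.10 (camera adjusted p = 0.378). The proliferation marker Mki67 fell by 0.32 (SE 0.05) and the topoisomerase gene Top2a by 0.18 (SE 0.05). The Top2a call was lost without Dor WT replicate 2 (-0.15, adjusted p = 0.0679) or Dor cKO replicate 1 (-0.15, adjusted p = 0.101), and with the length and GC trend removed (-0.09, adjusted p = 0.214).

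Of 26 cholesterol synthesis genes, 20 fell and 0 rose, or 22 and 0 adjusted over the list alone, with a median of -0.31 (camera adjusted p = 5.95e-13, and adjusted p = 0.0875 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, went from 1004 ± 16.3 to 734 ± 7.51 CPM and fell by 0.45 (SE 0.02, adjusted p = 1.01e-17). Cyp51, a later enzyme, fell by 0.38 (SE 0.04). Of 25 fatty acid and sphingolipid synthesis genes, 15 fell and 3 rose, or 15 and 4 adjusted over the list alone, with a median of -0.11 (camera adjusted p = 3.15e-08, and adjusted p = 0.108 with an estimated correlation). The desaturase gene Scd2 fell by 0.09 (SE 0.01) and Fads2 by 0.09 (SE 0.02), whereas Scd1 rose by 0.09 (SE 0.02). The list's mean was -0.22 and its lowest value -0.91, so these members do not show its larger falls. Fa2h, Ugt8a and Gal3st1 are also on the myelin list, so the results of these lists are not independent.

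**Figure D1:**
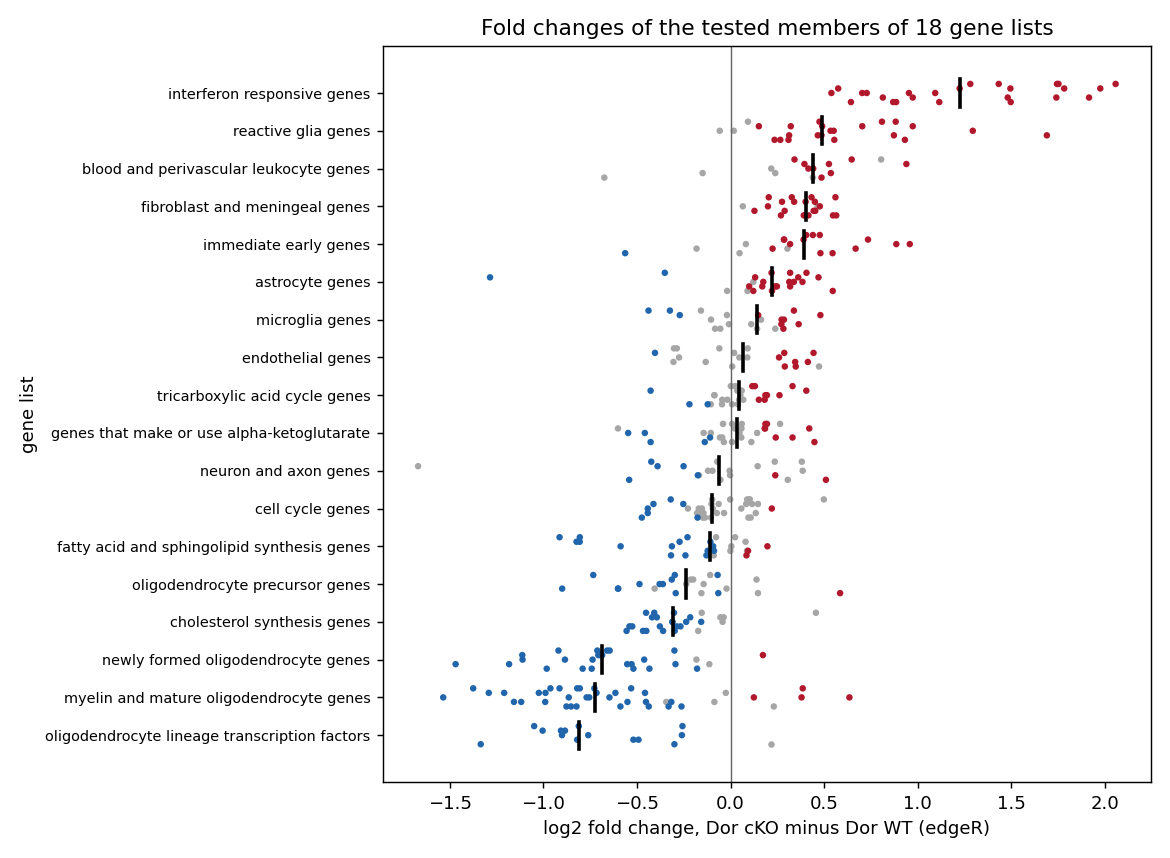
Log2 fold changes (Dor cKO minus Dor WT, x axis) of the tested members of 18 gene lists (y axis), with each list's median as a black bar. Red points rose and blue points fell at an edgeR adjusted p under 0.05, grey points did not pass, and medians run from -0.81 for the lineage transcription factors to 1.22 for the interferon responsive genes.

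Members of the list of genes that make or use alpha-ketoglutarate went both ways. Of 30 tested members, 8 rose and 5 fell, with the same counts adjusted over the list alone and a median of 0.03 (camera adjusted p = 0.666; fry up, adjusted p = 0.0386). The median was -0.02 without Dor WT replicate 1. Glul, which encodes glutamine synthetase, rose by 0.45 (SE 0.02, adjusted p = 1.19e-19) and Ogdh, a subunit of the alpha-ketoglutarate dehydrogenase complex, by 0.19 (SE 0.03). Psat1 and Phgdh, genes of serine synthesis, fell by 0.46 (SE 0.03) and 0.11 (SE 0.03). The Phgdh call was lost without Dor WT replicate 1 (-0.07, adjusted p = 0.114) or Dor cKO replicate 1 (-0.11, adjusted p = 0.0503). Of 28 tricarboxylic acid cycle genes, 9 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.04 (camera adjusted p = 0.322). Sdha rose by 0.15 (SE 0.03), Pdha1 rose by 0.12 (SE 0.03) and Acly fell by 0.12 (SE 0.03). The Pdha1 call was lost without Dor cKO replicate 2 (0.09, adjusted p = 0.0958). Of 33 genes for dioxygenases that depend on alpha-ketoglutarate, 3 rose and 2 fell, or 3 and 1 adjusted over the list alone (median 0.04, camera adjusted p = 0.637). The oxygen sensor gene Egln3 rose by 0.48 (SE 0.05), the lysyl hydroxylase gene Plod1 rose by 0.14 (SE 0.04) and the histone demethylase gene Kdm6b fell by 0.20 (SE 0.05). The Plod1 call was lost without Dor WT replicate 1 (0.12, adjusted p = 0.0541) or Dor cKO replicate 2 (0.11, adjusted p = 0.155), and the Kdm6b call without Dor cKO replicate 1 (-0.18, adjusted p = 0.0729).

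Of 75 nuclear oxidative phosphorylation genes, 15 rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 0.01 that turned to -0.01 with total count scaling (camera adjusted p = 0.441). Atp5g3, an ATP synthase subunit gene, rose by 0.16 (SE 0.03). Of 13 mitochondrially encoded genes, 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (median 0.10, camera adjusted p = 5.62e-03, and adjusted p = 0.343 with an estimated correlation). That median was 0.0155 with limma on log2(TPM + 1) and 0.22 with the trend on length and GC content removed. The respiratory chain genes mt-Co1 and mt-Cytb rose by 0.06 (SE 0.01) and 0.10 (SE 0.01). All genes with an mt- symbol, also those outside the list, took 4.75% and 4.7% of counts in Dor WT. They took 4.97% and 4.96% in Dor cKO. Of 22 glycolysis and lactate transport genes, 11 rose and 3 fell, or 11 and 4 adjusted over the list alone (median 0.09, camera adjusted p = 0.0381, and adjusted p = 0.327 with an estimated correlation). That call was also lost without Dor cKO replicate 2 (adjusted p = 0.0524), with total count scaling (adjusted p = 0.0872) and with the length and GC trend removed (adjusted p = 0.32). The enzyme genes Aldoa and Pkm rose by 0.16 (SE 0.02) and 0.08 (SE 0.02), and Gapdh fell by 0.05 (SE 0.02). The Pkm call was lost with the length and GC trend removed (0.0235, adjusted p = 0.402). The Gapdh call was lost with DESeq2 (adjusted p = 0.115) and without any of the 4 libraries in turn (-0.05 to -0.04, adjusted p = 0.0524 to 0.253).

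All 25 interferon responsive genes on the list rose, with the same count adjusted over the list alone, a median of 1.22 and a range of 0.54 to 2.06 (camera adjusted p = 1.29e-44, and adjusted p = 0.0483 with an estimated correlation). Ifit3, an antiviral effector gene, went from 68.2 ± 0.126 to 159 ± 7.52 CPM and rose by 1.22 (SE 0.04, adjusted p = 5.37e-19). Ifitm3 rose by 0.87 (SE 0.04) and Ifit2 by 0.73 (SE 0.05). Of the 12 largest rises among the genes eligible for naming, 7 were on this list, and the other 5 (Tgtp1, Dhx58, Iigp1, Ifi27l2a and Gbp10) are known to be induced by interferon. Tgtp1 rose by 2.07 (SE 0.19), Isg15 by 1.98 (SE 0.15), Dhx58 by 1.93 (SE 0.20), Irf7 by 1.92 (SE 0.12), Usp18 by 1.78 (SE 0.13) and Rsad2 by 1.75 (SE 0.17). They continued with Ifit1 at 1.74 (SE 0.08), Iigp1 at 1.69 (SE 0.11), Ifi27l2a at 1.58 (SE 0.11), Gbp10 at 1.57 (SE 0.14), Rtp4 at 1.50 (SE 0.14) and Oasl2 at 1.49 (SE 0.07). Tgtp1 and Gbp10 share reads with near-identical genes, and their values are uncertain to that extent.

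Of 24 reactive glia genes, 21 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.49 (camera adjusted p = 1.41e-20, and adjusted p = 0.149 with an estimated correlation). Of the list's members, 6 that are known to be induced by interferon, among them Iigp1 and Cxcl10, were singled out after their values were seen. These 6 rose by 0.49 to 1.69. Of the other 18 members, 15 rose, with a median of 0.39. Whether interferon also induces some of these 18 was not examined, so the split does not set the interferon response apart. Vim, an intermediate filament gene, rose by 0.15 (SE 0.01), the complement genes C4b and Serping1 by 0.47 (SE 0.02) and 0.55 (SE 0.03) and Serpina3n by 0.31 (SE 0.02). Of 23 astrocyte genes, 18 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.22 (camera adjusted p = 4.56e-12, and adjusted p = 0.108 with an estimated correlation). Gfap, the astrocyte filament gene, rose by 0.10 (SE 0.01), the gap junction gene Gja1 by 0.38 (SE 0.01) and the glutamate transporter gene Slc1a3 by 0.22 (SE 0.02).

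Of 21 fibroblast and meningeal genes, 19 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.40 (camera adjusted p = 4.53e-32, and adjusted p = 0.0483 with an estimated correlation). The growth factor gene Igf2 rose by 0.45 (SE 0.01) and the collagen genes Col1a2 and Col3a1 by 0.34 (SE 0.01) and 0.33 (SE 0.01). Of 15 leukocyte genes of blood and perivascular space, 9 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.44 (camera adjusted p = 2.73e-04, and adjusted p = 0.162 with an estimated correlation). The macrophage receptor genes Mrc1 and Cd163 rose by 0.49 (SE 0.04) and 0.53 (SE 0.07), and F13a1 by 0.44 (SE 0.05). Of 21 microglia genes, 8 rose and 3 fell, with the same counts adjusted over the list alone (median 0.14, camera adjusted p = 0.0728, and 0.0153 without a low-count filter). Csf1r, a growth factor receptor of microglia, rose by 0.34 (SE 0.03) and the complement gene C1qb by 0.27 (SE 0.05).

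Of 21 genes of disease-associated or phagocytic microglia, 7 rose and 5 fell, or 9 and 6 adjusted over the list alone, with a median of 0.14 and a mean of -0.08 (camera direction up, adjusted p = 0.637). Apoe, a lipid carrier gene, rose by 0.28 (SE 0.01), and Cd9 fell by 0.42 (SE 0.03). Of 20 endothelial genes, 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.147), with Cdh5 up by 0.41 (SE 0.04) and Ptprb having fallen by 0.40 (SE 0.07). Of 13 mural cell genes, 4 rose and 3 fell, with the same counts adjusted over the list alone. The median was 0.11, the mean -0.06 and the camera direction up (adjusted p = 0.188), and Vtn rose by 0.34 (SE 0.02). Of 20 neuron and axon genes, 5 fell and 2 rose, or 6 and 3 adjusted over the list alone (median -0.06, camera adjusted p = 0.355). The neurite genes Map2 and Gap43 fell by 0.42 (SE 0.03) and 0.39 (SE 0.05), and the neurofilament gene Nefl rose by 0.24 (SE 0.08). The Nefl call was lost with DESeq2 (adjusted p = 0.0898) and without Dor WT replicate 2 (0.18, adjusted p = 0.18), Dor cKO replicate 1 (0.21, adjusted p = 0.164) or Dor cKO replicate 2 (0.27, adjusted p = 0.055).

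**Figure D2:**
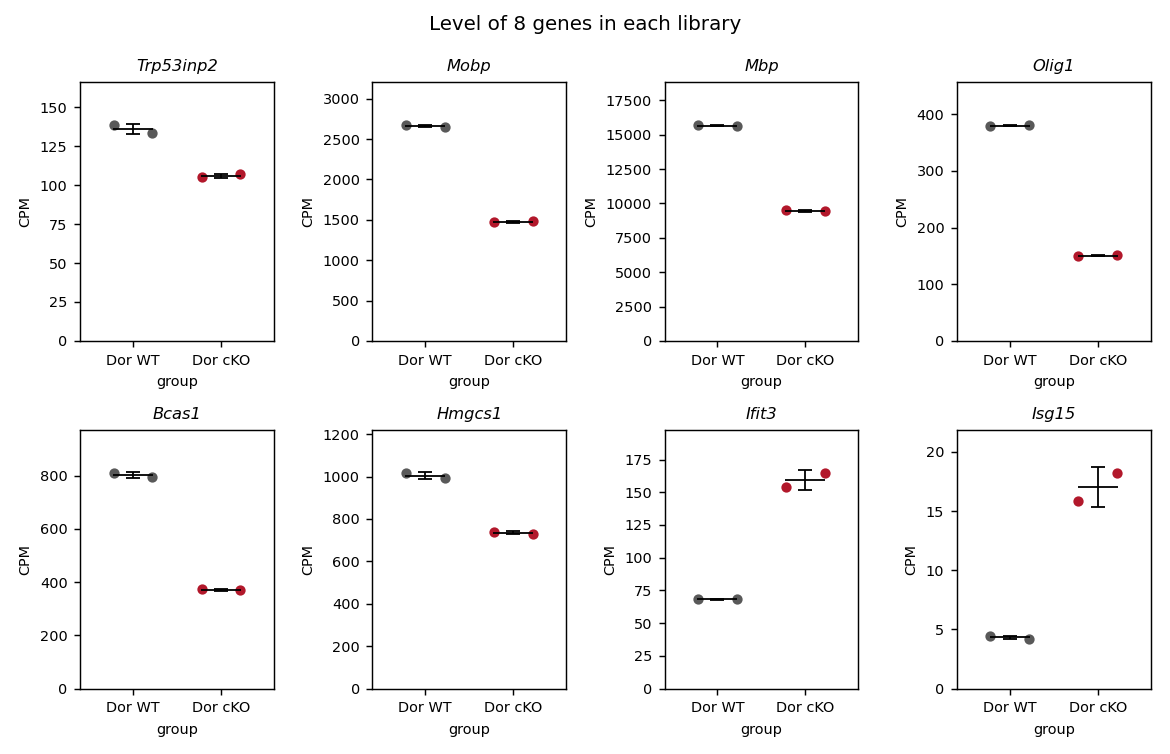
CPM (y axis, from 0) of 8 genes in Dor WT (grey) and Dor cKO (red); each point is a library and the bars give the mean and SD of 2 libraries. Mobp, Mbp, Olig1, Bcas1, Hmgcs1 and Trp53inp2 were lower in both Dor cKO libraries, and Ifit3 and Isg15 were higher in both.

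The 12 largest falls among the genes eligible for naming included hormone and secretory genes. Cga (chromosome 4, 34893779 to 34907370), the common alpha subunit of pituitary glycoprotein hormones, had 275 and 376 counts in Dor WT and 0 and 0 in Dor cKO, at least 115-fold lower against a floor of 3 counts per library. Chga, a granin of secretory granules, fell by 2.36 (SE 0.07, adjusted p = 2.25e-21), and the neuropeptide gene Npy by 2.30 (SE 0.17). Fndc3c1 fell by 4.81 (SE 0.28), the enamel matrix gene Ambn by 4.03 (SE 0.17), the sodium channel gene Scn7a by 2.93 (SE 0.13) and the transporter gene Abca8a by 2.49 (SE 0.17). Irs4, an insulin receptor substrate gene, fell by 1.94 (SE 0.11), the epithelial adhesion gene Epcam by 1.72 (SE 0.18), the Wnt receptor gene Fzd5 by 1.65 (SE 0.08) and the potassium channel gene Kcna1 by 1.61 (SE 0.13). Ermn completed this group. Of the 12, 7 are on the lists of pituitary and ventral hypothalamus genes given below, which were drawn up after these falls were seen. Whether these falls arose in the nerve or from adjoining tissue in the Dor WT libraries was not tested. With limma on log2(TPM + 1), whose pseudocount shrinks changes of genes with low TPM, Abca8a was at -0.81 and lost its call (adjusted p = 0.413).

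Of the stress and signalling lists, immediate early genes rose in 14 of 19 members and fell in 1, with the same counts adjusted over the list alone and a median of 0.39 (camera adjusted p = 4.02e-06, and adjusted p = 0.139 with an estimated correlation). The transcription factor genes Jund, Klf4 and Jun rose by 0.39 (SE 0.03), 0.55 (SE 0.05) and 0.22 (SE 0.04). Of 12 heat shock genes, 4 rose and 3 fell, or 4 and 5 adjusted over the list alone, with a median of -0.04, a mean of 0.11 and the camera direction up (adjusted p = 0.748). The small heat shock gene Hspb1 rose by 0.55 (SE 0.05), and the chaperone genes Hspa8 and Hsp90aa1 fell by 0.11 (SE 0.02) and 0.19 (SE 0.02). Of 17 unfolded protein response genes, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.0728, and 0.0153 with limma on log2(TPM + 1) or without a low-count filter and 0.0397 without Dor WT replicate 1), with the chaperone genes Hspa5 and Calr up by 0.19 (SE 0.02) and 0.17 (SE 0.02). Of 29 integrated stress response genes, 6 rose and 6 fell, or 7 and 6 adjusted over the list alone (median -0.02, camera adjusted p = 0.748). The amino acid transporter genes Slc7a11 and Slc3a2 rose by 0.25 (SE 0.03) and 0.27 (SE 0.03).

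Of 19 targets of p53, 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.197). The cell cycle inhibitor gene Cdkn1a rose by 0.45 (SE 0.06) and Ccng1 fell by 0.16 (SE 0.04). The Ccng1 call was lost with the length and GC trend removed (-0.06, adjusted p = 0.305). Of 38 autophagy and lysosome genes, 7 rose and 4 fell, with the same counts adjusted over the list alone. The median was 0.00405, the mean -0.00198 and the camera direction up (adjusted p = 0.666), and the median was -0.02 with total count scaling. The autophagy receptor gene Sqstm1 rose by 0.16 (SE 0.03) and the lysosomal genes Ctsb and Lamp2 by 0.15 (SE 0.02) and 0.14 (SE 0.02). Of 16 thyroid hormone responsive genes, 7 rose and 4 fell, with the same counts adjusted over the list alone (median 0.16, camera adjusted p = 0.637). The receptor gene Thra fell by 0.25 (SE 0.02) and Klf9 rose by 0.27 (SE 0.03). Of 75 cytosolic ribosomal protein genes, 23 fell and 8 rose, or 23 and 9 adjusted over the list alone (median -0.02, camera adjusted p = 0.469). The list passed camera downward with limma on log2(TPM + 1) (median -0.0785, adjusted p = 5.68e-09) and with the length and GC trend removed (-0.0757, adjusted p = 2.18e-04). Rpsa fell by 0.15 (SE 0.02) and Rpl3 by 0.07 (SE 0.02). The Rpl3 call was lost without Dor cKO replicate 1 (-0.07, adjusted p = 0.0718).

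By fry, which does not compare a list with other genes, each of the 14 lists called by camera passed in the direction given, and 13 lists that camera did not call passed as well. Of these, fry gave the direction up for 8: microglia (adjusted p = 0.0012), nuclear oxidative phosphorylation (0.00297), tricarboxylic acid cycle (0.00515), p53 target (0.0243), endothelial (0.0253), unfolded protein response (0.0253), thyroid hormone responsive (0.0382) and alpha-ketoglutarate genes. It gave the direction down for 5: cell cycle (adjusted p = 0.0106), neuron and axon (0.0157), lens (0.0216), sex chromosome marker (0.0382) and red blood cell genes (0.045). That direction differed in sign from the median (0.50) and mean (0.20) of the sex chromosome markers, of which 4 rose and only Xist fell, and from the mean (0.05) of the lens genes.

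Lists for other tissues gave few calls. Of 3 tested retina genes 1 rose, and of 3 tested adipocyte genes 0 rose and 0 fell with edgeR, too few for camera in both cases. The adipocyte list had 0 members at an unadjusted p under 0.05 and 0 calls with DESeq2 or limma. Of 5 tested pigment epithelium genes 1 fell and 0 rose, with a median of 0.41, a mean of -0.78 and the camera direction down (adjusted p = 0.559). The gene that fell was Lrat, a retinol-esterifying enzyme, from 5.27 ± 0.286 to 0.120 ± 0.17 CPM. Of 5 tested lens genes 1 fell and 0 rose, with a median of -0.00029 that lay above 0 with RLE scaling, a mean of 0.05 and the camera direction down (adjusted p = 0.723). Of 12 tested skeletal muscle genes 0 rose and 0 fell with edgeR (camera adjusted p = 0.729), with 1 at an unadjusted p under 0.05 and 0 calls with DESeq2 or limma. Of 10 tested Schwann cell genes 1 rose, Pmp22 at 0.24 (SE 0.03), and 0 fell (camera adjusted p = 0.666). Of 8 tested red blood cell genes 3 fell and 0 rose (median -0.21, camera adjusted p = 0.192), with the globin gene Hbb-bs having fallen by 0.14 (SE 0.03). That list passed camera with limma on log2(TPM + 1) (-0.25, adjusted p = 0.00211) and with the length and GC trend removed (-0.23, adjusted p = 0.0194). For each of these lists the counts adjusted over the list alone were the same, except red blood cell genes, of which 4 fell.

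The sex chromosome markers differed between the groups in the same libraries as the gene groups described. Xist, the transcript that silences an X chromosome in females, went from 574 ± 0.291 to 267 ± 7.65 CPM and fell by 1.10 (SE 0.02, adjusted p = 3.44e-24). The Y-linked gene Ddx3y went from 39.1 ± 0.978 to 59.0 ± 1.57 CPM and rose by 0.59 (SE 0.06, adjusted p = 1.2e-08), and Eif2s3y, Kdm5d and Uty rose by 0.47 (SE 0.10), 0.53 (SE 0.13) and 0.50 (SE 0.14). The Kdm5d call was lost without Dor WT replicate 1 (0.37, adjusted p = 0.0548) or Dor cKO replicate 1 (0.43, adjusted p = 0.0646), and the Uty call without Dor WT replicate 1 (0.39, adjusted p = 0.0653) or Dor cKO replicate 2 (0.45, adjusted p = 0.0692). Both Xist and the Y-linked transcripts were counted in each of the 4 libraries. Of 5 tested markers 4 rose and 1 fell, with the same counts adjusted over the list alone, a median of 0.50 and the camera direction down (adjusted p = 0.192). The mean fragment length was 259.6 and 260 bases in Dor WT and 245.5 and 245.3 bases in Dor cKO. The gene model CT010467.1 took 0.232% and 0.23% of counts in Dor WT and 0.615% and 0.624% in Dor cKO. It rose by 1.44 (SE 0.01), and Lars2 rose by 1.44 (SE 0.05). Both were chosen after their values were seen. Whether these rises reflect expression or the preparation of the libraries was not tested.

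**Figure D3:**
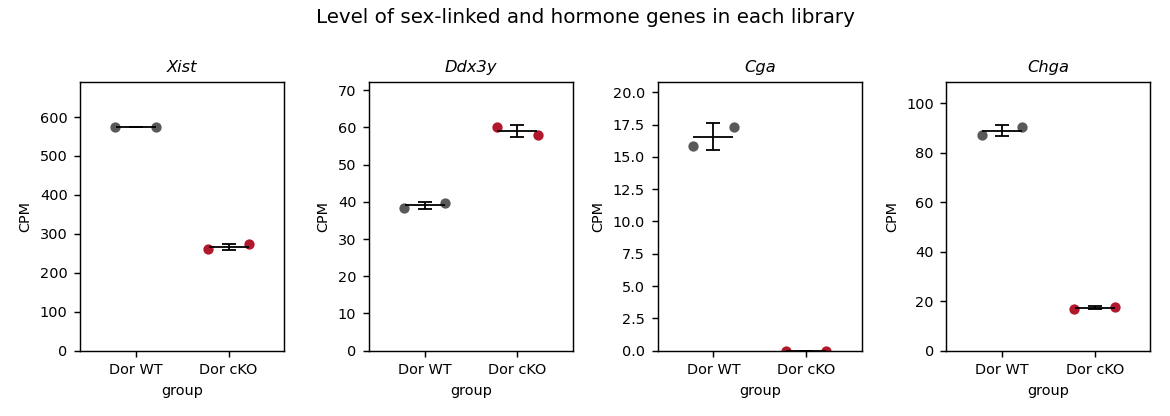
CPM (y axis, from 0) of Xist, the Y-linked gene Ddx3y and the secretory genes Cga and Chga in Dor WT (grey) and Dor cKO (red); each point is a library and the bars give the mean and SD of 2 libraries. Xist, Cga and Chga were lower and Ddx3y was higher in both Dor cKO libraries.

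The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. That spread was 2.34 times counting error in Dor WT and 1.91 times in Dor cKO, which does not tell splits of the same RNA from separate animals. Levels that depend on the animals and the dissection were also close within a group. Xist was at 573.8 and 574.2 CPM in Dor WT and 262.0 and 272.8 CPM in Dor cKO. Cga was at 15.8 and 17.3 CPM in Dor WT. Splits of the same RNA would give such values, so the p-values need not concern the genotype. With the biological coefficient of variation set at 0.1 for every gene, a value chosen after that spread was seen, 703 genes were higher and 891 lower, and limma on log2(TPM + 1) called 666 and 722. Of the named genes, 58 lost their call with the set coefficient and 38 with limma on log2(TPM + 1).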

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

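The length and GC trend removal and the coefficient of variation set at 0.1 were chosen after seeing the data; all other alternatives were planned. Counts of genes higher and lower stayed within 1.5 times with DESeq2 (1801 and 1656), both other scalings and filters, the fit without the robust option, the trend removal, and without mitochondrial and haemoglobin genes. Leaving out a library in turn, with the lone sample assumed to vary like the other group, gave 1782 to 2184 higher and 1670 to 2073 lower, and Trp53inp2 at -0.38 to -0.33. The counts moved to 123 and 172 with a log2 fold change of at least 1, to 666 and 722 with limma on log2(TPM + 1), of which 632 and 677 were shared, and to 703 and 891 with the set coefficient, of which 611 and 775 were shared. Trp53inp2 lost its call with limma on TPM (-0.28, adjusted p = 0.078) and with the set coefficient (-0.36, adjusted p = 0.111). The set coefficient was used with a likelihood ratio test in place of the quasi-likelihood test. Whether the coefficient or the test lost the calls was not tested, and for limma the cause was not tested either. The replicate numbers did not pair the libraries (correlation of deviations across genes -0.0121); the replicate block gave 2562 higher and 2409 lower, and a lens median of 0.000318. With the preset correlation, the lists called by camera, except glycolysis, kept direction and call under each alternative run for them. With an estimated correlation, glycolysis and 8 others lost the call: precursor, astrocyte, reactive glia, leukocyte, mitochondrially encoded, cholesterol, fatty acid and immediate early genes (adjusted p = 0.0875 to 0.343). Also, the mitochondrially encoded median was 0.0155 with limma on TPM and 0.22 with the trend removed, and the fatty acid median -0.17 with limma on TPM. Other lists changed, and the cause was not tested. With total count scaling the median was -0.0161 for autophagy, -0.00979 for oxidative phosphorylation and 0.0680 for glycolysis, whose call was lost. With limma on TPM it was -0.0398 for autophagy, -0.0528 for oxidative phosphorylation and -0.00532 for mural cell genes, and ribosomal protein (-0.0785), red blood cell (-0.25) and unfolded protein response genes (0.0961) passed. With the trend removed it was -0.00994 for autophagy, -0.0146 for oxidative phosphorylation and 0.0466 for glycolysis, whose call was lost, and ribosomal protein (-0.0757) and red blood cell genes (-0.23) passed. Glycolysis was also not called with the set coefficient (0.0882). Without a low-count filter microglia (0.15) and unfolded protein response genes (0.13) passed. The lens median was 0.00067 with RLE scaling and 0.000475 without mitochondrial and haemoglobin genes. Over libraries left out, medians ran from -0.0186 (without Dor cKO replicate 1) to 0.21 for Schwann cell genes, -0.0107 (without Dor cKO replicate 1) to 0.0170 for autophagy, -0.0189 (without Dor WT replicate 1) to 0.0643 for alpha-ketoglutarate genes, 0.0809 to 0.0874 for glycolysis, whose call was lost without Dor cKO replicate 2 (adjusted p = 0.0524), and 0.0983 to 0.125 for the unfolded protein response, which passed without Dor WT replicate 1 (adjusted p = 0.0397). Medians of lists that camera did not call moved by over 1.5 times too, among them endothelial (0.0366 to 0.195), mural (0.0430 to 0.196), cell cycle (-0.125 to -0.0395), neuron (-0.121 to -0.0397), p53 (0.0343 to 0.134) and microglia genes (0.0921 to 0.174). Avp turned to -0.0101 with total count scaling, -0.0614 with limma on TPM and -0.0461 with the trend removed, and ran from -0.0386 (without Dor WT replicate 1) to 0.0638, with -0.0229 without Dor cKO replicate 2. Named genes otherwise kept their direction: of 2081 values under alternatives, 1946 kept direction and side of the threshold and 130 lost the call, 58 of these with the set coefficient and 38 with limma on TPM. The value of a called named gene moved by over 1.5 times for 16 of 137 with limma on TPM and 16 with the trend removed. It did so for 1 gene each without Dor WT replicate 1, Dor cKO replicate 1 and Dor cKO replicate 2. DESeq2 was not run for camera. Oprd1, with 0 to 5 counts per library, was not tested. At this depth and group size, with the same dispersion for every gene and few genes changed, the simulated test recovered 18% of genes changed by 0.2. Depth was not varied.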

Other observations

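In this part the lists of pituitary, hypothalamic and X-linked genes and the tests of other cell types, female and male share, dissection and leukocytes were chosen after the results were seen, and only the removal of the length and GC trend was set before its result. Of 20 pituitary genes, 14 were tested, 11 fell and 1 rose, with a median of -1.86 that stayed at -1.86 with genes at 0 set to their bound. Scg2, a secretogranin gene, went from 112 ± 3.99 to 45.4 ± 2.73 CPM and fell by 1.31 (SE 0.05). Gh, which encodes growth hormone, had 121 and 123 counts in Dor WT and 3 and 0 in Dor cKO, and the pituitary transcription factor gene Lhx3 had 23 and 23 against 0 and 0, at least 8.27-fold lower against a floor of 3 counts per library. The hormone precursor gene Pomc fell by 1.99 (SE 0.26) and Cck by 2.78 (SE 0.29). Of 24 tested genes of ventral hypothalamus and tanycytes, the glia that line the floor of the ventricle there, 12 fell and 2 rose, with a median of -0.30. Because these lists were drawn up after the falls were seen, their counts and medians describe the libraries and test nothing. Rax fell by 3.18 (SE 0.47), Nkx2-1 by 1.94 (SE 0.26) and the deiodinase gene Dio2 by 1.15 (SE 0.07). Avp, the vasopressin gene and the most abundant member, was at 346 ± 17.3 CPM in Dor WT and 349 ± 11.4 CPM in Dor cKO (edgeR adjusted p = 0.862), and Oxt rose by 0.40 (SE 0.07). Of the 12 largest falls, 7 are on these lists, 1 member is also on another list, and expression of these genes by the nerve itself was not analysed here.

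Single members of the lists went apart, and these genes were chosen after their values were seen. Among genes that make alpha-ketoglutarate, the cytosolic isocitrate dehydrogenase gene Idh1 fell from 241 ± 8.75 to 179 ± 3.84 CPM (log2 fold change -0.43, SE 0.03, edgeR adjusted p = 9.02e-12), and the mitochondrial Idh2 rose from 131 ± 3.995 to 164 ± 1.97 CPM (0.33, SE 0.04, adjusted p = 1.79e-08). Olig2 fell by 0.49 (SE 0.04), against a fall by 1.33 (SE 0.03) of its neighbour Olig1 on chromosome 16. Apod, a lipocalin gene listed with myelin genes, rose by 0.64 (SE 0.02) and the prostaglandin D synthase gene Ptgds by 0.52 (SE 0.01). Among thyroid hormone responsive genes, Hr fell by 0.57 (SE 0.06). Of 4 X-linked genes with a Y-linked copy, Eif2s3x fell by 0.24 (SE 0.03), and the others did not pass (list median -0.105).

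The oligodendrocyte and myelin genes were lower in Dor cKO in libraries that also differed in sex markers, fragment length and pituitary genes. Fewer oligodendrocytes, with all other cell types in unchanged proportion and expression, would raise the lists of 6 other cell types alike. Their medians ran from -0.06 for neurons to 0.40 for fibroblasts. Such a spread was rarely reached when genes were exchanged between the lists (permutation p = 0.00759, 100000 draws). Expression changes within those cell types, or tissue from beside the nerve, would also spread the medians. The test therefore does not decide whether oligodendrocytes were fewer. Removing the length and GC trend left the myelin median at -0.735 (camera adjusted p = 1.48e-87). A smaller share of female RNA, solved as 45% in Dor WT and 20.7% in Dor cKO, could lower a gene at most as far as Xist, and 7 of 80 lineage and myelin genes (Ermn, Neu4, Opalin, Olig1, Gjc3, Mal and Gpr17) fell further by more than 2 combined SE; for the other 73, with a median of -0.66, sex and genotype cannot be told apart because no library holds RNA of a single sex, and female nerves would need a level 5.69 times that of males. A more myelinated stretch of the nerve or chiasm in the Dor WT libraries and the genotype cannot be told apart either: the 31 pituitary and hypothalamic genes outside the 12 largest falls had a median of -0.41, but they were listed after the falls were seen. A change in oligodendrocytes together with other cell types, the genotype, the litter and the age also stay open and were not tested. The preparation of the libraries stays open too, apart from the length and GC trend. Only the names of the Dor WT tables carry a tag that reads like an age.

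All 25 interferon responsive genes were higher in both Dor cKO libraries than in both Dor WT libraries. More leukocytes or microglia of unchanged expression would raise them no further than the cells' own markers. The interferon list median exceeded that of the leukocyte list by 0.784 (95% bootstrap interval over genes 0.448 to 1.14), and the microglia median was 0.14. However, the leukocyte list mixes cell types, and its members ran from -0.674 to 0.939. More cells of 1 type, or cells with higher expression of interferon responsive genes, could raise the list further. The comparison therefore does not decide whether such cells were the source. A larger share of male RNA could raise a gene at most as far as a Y-linked gene. The interferon list median exceeded the rise of Ddx3y, the Y-linked marker that rose most, by 0.631 (95% bootstrap interval over genes and the SE of Ddx3y 0.284 to 0.982). Of the 25 members, 19 rose further than Ddx3y by more than 2 combined SE. For the others, sex and genotype cannot be told apart. Bootstrap intervals over genes treat the members of a list as independent. Removing the length and GC trend left the interferon median at 1.23 (camera adjusted p = 2.91e-44). As a hypothesis found and examined on the same libraries, the rise may come from a response to interferon. The genotype, the age and the dissection stay open and were not tested for this list. The preparation of the libraries stays open as well, apart from the length and GC trend.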
